A study of Homo sapiens with 6 samples.

How the data were processed

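Total RNA was extracted with TRIzol and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, and the build GRCh38. The authors deposited a table of FPKM values, fragments scaled by gene length and library size, for 58735 genes in 6 libraries, with gene positions and biotypes. All 58735 gene identifiers were found in GENCODE 29, and 58724 had the same start and end there.

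Multiplying each deposited FPKM value by gene length gave whole multiples of 1 step per library for 100% of values above 0, within 0.02 reads. The reads rebuilt in this way totalled 26219551, 27578299 and 27896243 in NC replicates 1 to 3, and 26388114, 28261073 and 29143875 in si-LINC01547 replicates 1 to 3. The reads implied as the denominator equalled a median-of-ratios scaling of these totals (ratio 1 in each library), so another median-of-ratios scaling moved next to nothing. As the values are FPKM, the main test used them on the log scale, and limma's voom was run on the rebuilt reads as an alternative.

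Differences were tested with limma 3.58.1 in R 4.3.3 (linear model on group, empirical Bayes with a mean trend) on log2(FPKM + 1), over 14235 genes with a mean of at least 0.5 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate those of low genes. Gene lists with at least 5 genes tested were compared with limma's camera at a preset correlation of 0.01, with an estimated correlation and with limma's fry. Neighbours of LINC01547 were genes within 500 kb. Test, filter, 39 lists, alternatives and the rule for named genes were set before the data were examined.

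Named genes were LINC01547; up to 12 genes each way with the largest difference among those passing, at a mean of at least 1 FPKM in the higher group and with no overlap; for each list called, up to 4 passing members, or the 2 most abundant where none passed; up to 2 members of other lists with at least 3 passing; the 2 most abundant genes of each cell marker list; neighbours that passed, or the 2 with the smallest p; and, with fewer than 10 genes passing, the 5 with the smallest p each way. Members passing over a list alone were named in addition, after their values were seen. Genes on the Y chromosome and XIST were left out of the tables written. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between libraries.

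The gene test was tested on simulated counts with real means and library sizes. With the spread of all 6 libraries and 14230 genes tested, it recovered 0% of 94 genes changed 2-fold and 30.9% of 94 changed 4-fold, with 0 false calls. With the spread found without si-LINC01547 replicate 1 and 14184 genes tested, it recovered 35.7% of 98 genes changed 2-fold and 78.3% of 92 changed 4-fold, with 1 false call. Each gene was drawn on its own, with the same spread in every library. Shifts of many genes together in a single library were not simulated, so recovery and false calls on the real data can differ. Alternatives were another pseudocount (0.1), other filters, scalings, weights and gene classes, voom on rebuilt reads, the replicate number as a block, and leaving out each library. Added after seeing the data were the fit without both libraries numbered 1, 2 further weightings and removal of a trend on gene length and GC content. Array weights were planned without naming an estimator. Restricted maximum likelihood, limma's default, stopped before convergence, so the gene-by-gene estimator, chosen after this was seen, is reported as array weights and the default is given beside it. A scan of words of 7 bases covered genes with a mean of at least 1 FPKM and a 3' UTR of at least 50 bases, in Python 3.11.15 with numpy 2.4.6. On simulated values it ranked a word planted with a decrease of 0.5 or 0.2 SD at 1, and gave z = -0.894 to a word with none.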

Results

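RNA was sequenced from 6 human libraries labelled Hep3B, a cell line derived from a hepatocellular carcinoma. The labels put 3 libraries in a negative control group (NC) and 3 in a group in which the long non-coding RNA LINC01547 was silenced with small interfering RNA (si-LINC01547). The sample labels give the source as xenograft, while the series design speaks of Hep3B cells. Nothing in the labels says whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries. The reads behind the deposited values ranged from 26219551 in NC replicate 1 to 29143875 in si-LINC01547 replicate 3.

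The first comparison asked whether the silenced transcript was lower in the libraries labelled si-LINC01547. LINC01547 (ENSG00000183250), a long intergenic non-coding RNA on the minus strand of chromosome 21 from 44932814 to 44939913 (GRCh38), stood at 3.39 ± 0.748 FPKM in NC (SD, n = 3) and at 0.853 ± 0.387 FPKM in si-LINC01547 (SD, n = 3). The si-LINC01547 mean was 25.2% of the NC mean. Single libraries held 4.11, 2.62 and 3.44 FPKM in NC and 0.468, 1.24 and 0.851 FPKM in si-LINC01547, so the groups did not overlap. Between 27 and 277 reads of the transcript lay behind these values. The difference was -1.25 on the log2(FPKM + 1) scale (SE 0.227), with a limma adjusted p of 0.57. The exact permutation test, two-sided, gave 0.1, the smallest p that 3 libraries against 3 allow. With array weights, which give less weight to libraries far from their group, the limma adjusted p was 0.0072 and the log2 difference -1.07. These weights were estimated from the same libraries, at 0.0622 for si-LINC01547 replicate 1 and 5.63 for NC replicate 3, so that p may be too small. Over all alternatives the limma adjusted p ranged from 0.0012 to 0.999 and the log2 difference from -2.00 to -0.95. The annotation places AL844908.1 over part of the same interval, and whether counting used strand is not given in the sources used here.

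**Figure D1:**
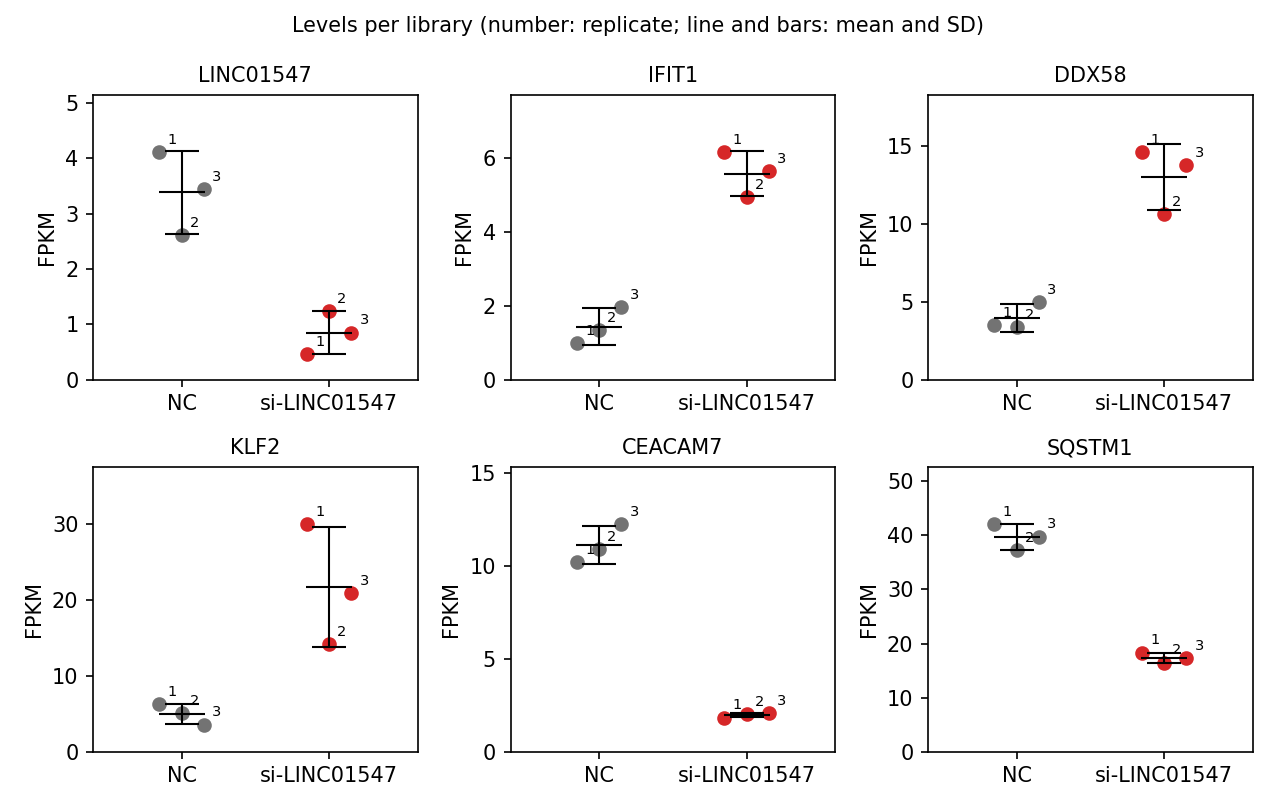
FPKM (vertical axes, from 0) of LINC01547, IFIT1, DDX58, KLF2, CEACAM7 and SQSTM1 in the 3 NC (grey) and 3 si-LINC01547 (red) libraries; numbers give the replicate, and the lines and bars the mean and SD of a group. In each panel the groups do not overlap, for example 0.468 to 1.24 FPKM of LINC01547 in si-LINC01547 against 2.62 to 4.11 in NC, although no gene shown passed the limma threshold over all genes.

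The second comparison asked which other transcripts differed between the groups. The labels name no other silencing RNA against LINC01547, so loss of LINC01547 and other effects of the RNA used cannot be told apart. The 5 smallest p-values among higher genes belonged to IFIT1, DDX58, CT45A10, RF00425 and KLF2. IFIT1 (ENSG00000185745, chromosome 10 from 89392546 to 89406486), an antiviral RNA-binding protein, averaged 1.43 ± 0.496 FPKM in NC and 5.57 ± 0.614 FPKM in si-LINC01547 (SD, n = 3 each). DDX58 (ENSG00000107201, chromosome 9 from 32455705 to 32526324), the RNA sensor RIG-I, averaged 3.97 ± 0.907 FPKM in NC and 13.03 ± 2.12 FPKM in si-LINC01547. KLF2 (ENSG00000127528, chromosome 19 from 16324817 to 16327874), a zinc finger transcription factor, averaged 5.01 ± 1.35 FPKM in NC and 21.7 ± 7.93 FPKM in si-LINC01547. Among lower genes, CEACAM7 (ENSG00000007306, chromosome 19 from 41673307 to 41706976), a cell surface glycoprotein, averaged 11.1 ± 1.04 FPKM in NC and 1.98 ± 0.12 FPKM in si-LINC01547.

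None of these passed the test, although in each the 3 values of a group lay on one side of the other 3. With limma, 0 of 14235 genes had an adjusted p under 0.05, and 609 had an unadjusted p under 0.05, of which 201 were higher and 408 lower in si-LINC01547; with no effect 711.75 would be expected. Voom on the rebuilt reads also called 0 genes, with 572 at an unadjusted p under 0.05. Without si-LINC01547 replicate 1 limma called 0 genes too, with 1496 at an unadjusted p under 0.05. Without both libraries numbered 1, a fit chosen after seeing the data, limma again called 0 genes (smallest adjusted p 0.099). In that fit 3304 genes had an unadjusted p under 0.05. With all libraries the smallest limma adjusted p was 0.078, for CEACAM7 (log2 difference -2.02, SE 0.159). The other genes with the smallest p had a limma adjusted p of 0.447, or 0.469 for KLF2. On the lower side these were DPEP1, a membrane dipeptidase, at 32.7 and 9.83 FPKM, VTN, the adhesion protein vitronectin, at 3.69 and 1.01 FPKM, CDH17, an intestinal cadherin, at 3.51 and 1.10 FPKM, and SQSTM1, the autophagy receptor p62, at 39.7 and 17.4 FPKM in NC and si-LINC01547. The annotation places SARM1 over part of VTN, MGAT4B over part of SQSTM1 and LIPA over part of IFIT1. On the higher side, CT45A10, a cancer-testis antigen with near-identical family members among which reads can be split, averaged 5.75 and 15.97 FPKM. RF00425, a small RNA inside DMGDH, was at 0.299 FPKM in NC replicate 1, at 0 in the other NC libraries and between 1.21 and 2.20 FPKM in si-LINC01547. It spans only 79220942 to 79221073 on chromosome 5, so few reads lie behind these values. Values of the groups did not overlap for 1875 genes, 13.2% of those tested, where chance gives 10%; the division of NC replicate 1 with si-LINC01547 replicates 2 and 3 against the rest gave 4179. Array weights, which gave si-LINC01547 replicate 1 a weight of 0.0622, led limma to call 799 genes at an adjusted p under 0.05, 287 higher and 512 lower; another division of the same 6 libraries gave 2223.

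The library of si-LINC01547 replicate 1 stood farthest apart, and that of NC replicate 1 less so. The Pearson correlation of log2 values across genes, which are not independent replicates, was 0.84 to 0.911 between si-LINC01547 replicate 1 and the other libraries. Among the other 5 libraries it was 0.955 to 0.987, with pairs that hold NC replicate 1 at 0.955 to 0.964 and the rest at 0.973 to 0.987. Ribosomal protein transcripts took 12.1% of the reads in si-LINC01547 replicate 1 and 3.67% to 5.48% in the others. NC replicate 1 held 11.4% mitochondrial reads, against 5.49% to 6.87% in the other libraries.

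**Figure D2:**
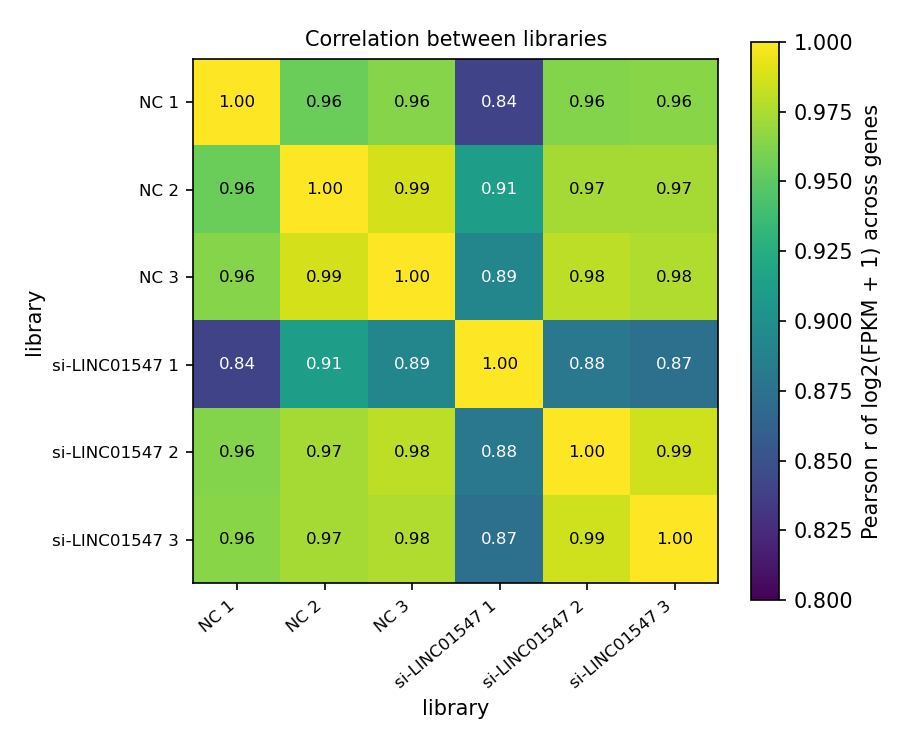
Pearson correlation of log2(FPKM + 1) across the genes tested between each pair of the 6 libraries (both axes: library; colour: r, from 0.8 to 1). si-LINC01547 replicate 1 shows the lowest values, down to 0.84 with NC replicate 1.

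Of the 39 gene lists fixed before the data were examined, 35 had at least 5 genes tested, and 9 differed by limma's camera test at a preset correlation of 0.01. The interferon response list rose (camera adjusted p = 7.1e-05, median log2 difference 0.15), with 22 of 31 members higher and 9 lower; adjusted p = 0.502 with an estimated correlation. The correlation was estimated at 0.046 for this list. No member passed over all genes tested, and 6 were higher adjusted over the list alone: IFIT1, IFIT2, IFIT3, IFI44, OASL and DDX58. IFIT2 averaged 4.48 ± 1.95 FPKM in NC and 16.5 ± 3.19 FPKM in si-LINC01547, and OASL 2.61 ± 0.838 and 11.99 ± 4.25 FPKM (SD, n = 3 each). The most abundant members, ISG15 and BST2, averaged 162 ± 67.5 and 61.5 ± 18.9 FPKM in NC, and 331 ± 194 and 117 ± 61.9 FPKM in si-LINC01547, with the highest values in replicate 1, at 554 and 188 FPKM. Without that library their log2 differences went from 0.98 to 0.54 and from 0.85 to 0.44, and without NC replicate 1 that of ISG15 was 0.57. Without both libraries numbered 1 the differences of ISG15 and BST2 were only 0.12 and 0.17. Without si-LINC01547 replicate 1 the list still rose (camera adjusted p = 1.1e-04, median 0.22). Over all alternatives with the preset correlation its camera adjusted p ranged from 8.5e-06 to 0.014. Its median was 0.068 without NC replicate 1, 0.23 without NC replicate 2 and 0.24 without si-LINC01547 replicate 2, and ranged from 0.048 to 0.24 over the alternatives.

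The cytosolic ribosomal protein list rose (camera adjusted p = 2.6e-09, median 0.60), with all 62 members higher and none passing over all genes or adjusted over the list alone; adjusted p = 0.591 with an estimated correlation. RPL13A was at 4246 FPKM in si-LINC01547 replicate 1 and between 804 and 1124 FPKM in the other 5 libraries, and RPS12 at 2880 and between 471 and 870 FPKM. Many processed pseudogenes share sequence with these transcripts. Without si-LINC01547 replicate 1 the median was 0.0065 and the camera direction turned, with an adjusted p of 0.953. Without both libraries numbered 1 the list passed as lower (camera adjusted p = 0.038, median -0.12), and with array weights the direction turned with no call (0.918). Where it rose, its lowest camera adjusted p over the alternatives was 2.1e-17, with libraries rescaled to the same total. Without si-LINC01547 replicate 2 the median was 0.93. The nuclear oxidative phosphorylation list rose with all libraries (camera adjusted p = 0.0045, median 0.30; adjusted p = 0.69 with an estimated correlation) and fell without si-LINC01547 replicate 1 (camera adjusted p = 2.2e-05, median -0.18). It also fell without both libraries numbered 1 (camera adjusted p = 7.9e-11, median -0.30) and with array weights (8.3e-06, median -0.22), each at the preset correlation. With all libraries the correlation was estimated at 0.81 for this list and 0.94 for the ribosomal protein list, far above the preset 0.01. It was not estimated in the other fits, so their p-values may be too small. Without NC replicate 1 its call ended (camera adjusted p = 0.23, median 0.18, the highest p over the alternatives), as it did with quantile normalization (0.136), and without si-LINC01547 replicates 2 or 3 its median was 0.56 or 0.55. Its most abundant members ATP5F1B, of the ATP synthase, and NDUFS5, of complex I, were at 636 and 557 FPKM in si-LINC01547 replicate 1, against at most 409 and 171 FPKM elsewhere.

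Heat shock and DNA replication lists rose as well (camera adjusted p = 0.0032 for each, medians 0.31 and 0.20), with no member passing; adjusted p = 0.546 and 0.502 with an estimated correlation. The chaperones HSP90AA1 and HSP90AB1 averaged 240 ± 37.9 and 427 ± 22.3 FPKM in NC, and 353 ± 184 and 537 ± 61.5 FPKM in si-LINC01547. HSP90AA1 was at 564 FPKM in si-LINC01547 replicate 1 and at 229 and 265 FPKM in replicates 2 and 3, and without replicate 1 its log2 difference went from 0.45 to 0.050. The replication clamp PCNA averaged 156 ± 45.4 and 299.9 ± 206 FPKM, and RRM1, a subunit of ribonucleotide reductase, 107 ± 3.07 and 105 ± 24.3 FPKM. PCNA was at 538 FPKM in si-LINC01547 replicate 1 and at 172 and 190 FPKM in replicates 2 and 3, and without replicate 1 its log2 difference went from 0.78 to 0.25. Without si-LINC01547 replicate 1 the heat shock call ended (camera adjusted p = 0.223, median 0.099, the highest p over the alternatives; lowest 9.6e-05), as it did with quantile normalization (0.071), with array weights (0.116) and without both libraries numbered 1 (0.179). The DNA replication list had a camera adjusted p of 0.027 without that library, in a range of 0.0018 to 0.291 over the alternatives, and its call ended with array weights (0.138) and without both libraries numbered 1 (0.291).

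The lists that fell were fatty acid synthesis and storage (camera adjusted p = 3.6e-04, median -0.24), extracellular matrix (4.8e-04, median -0.41), hepatocyte secreted proteins (0.02, median -0.11) and NRF2 antioxidant and ferroptosis genes (0.025, median -0.10). With an estimated correlation their adjusted p = 0.502, 0.591, 0.502 and 0.502. The desaturase SCD averaged 264 ± 77.6 FPKM in NC and 155 ± 54.8 FPKM in si-LINC01547, and the acyltransferase AGPAT2 70.8 ± 10.9 and 73.6 ± 29.5 FPKM, with SCD at 96.4 and AGPAT2 at 108 FPKM in si-LINC01547 replicate 1. In replicates 2 and 3 SCD was at 165 and 205 FPKM and AGPAT2 at 55.1 and 58.0 FPKM. Without replicate 1 the log2 difference of SCD went from -0.79 to -0.49. In the matrix list, LAMB3 and AGRN were at 20.7 and 21.9 FPKM in si-LINC01547 replicate 1 and between 65.2 and 109 FPKM elsewhere, and without that library the call ended (camera adjusted p = 0.783, median -0.03). It ended without NC replicate 1 as well (camera adjusted p = 0.061), in a range of 1.3e-05 to 0.783 over the alternatives. Without si-LINC01547 replicate 2 the matrix median was -0.67 and without replicate 3 -0.62. The fatty acid median was -0.12 without si-LINC01547 replicate 1 and -0.36 without replicate 3, with camera adjusted p from 1.3e-04 to 0.418 over the alternatives; its call ended with array weights (0.187) and without both libraries numbered 1 (0.418). Of the hepatocyte list 5 of 41 genes were tested; VTN was lower adjusted over the list alone, F12 averaged 5.35 and 5.15 FPKM, with 7.43 FPKM in si-LINC01547 replicate 1, and RBP4 5.03 and 3.21 FPKM. NC replicate 1 held 2.99 FPKM of RBP4, within the 2.90 to 3.52 FPKM of si-LINC01547, and its log2 difference of -0.47 went to -0.74 without that library and to -0.24 without NC replicate 2. ALB, the serum albumin gene, stayed at or under 0.0545 FPKM in all 6 libraries. The hepatocyte call ended without NC replicate 2 and without si-LINC01547 replicates 2 or 3 (camera adjusted p = 0.138, 0.195 and 0.127; range over the alternatives 0.0039 to 0.390, the highest with no filter on low values), and its median was -0.33 without si-LINC01547 replicate 1, -0.20 without NC replicate 3 and -0.066 without NC replicate 2. The NRF2 call ended without the same libraries (camera adjusted p = 0.113, 0.354 and 0.127; range 7.8e-05 to 0.354) and with a mean of at least 5 FPKM as the filter (0.061, median -0.027), with medians of -0.0017 without si-LINC01547 replicate 2, -0.065 without replicate 3, -0.21 without replicate 1 and -0.16 without NC replicate 3. The NRF2 call held without si-LINC01547 replicate 1 (camera adjusted p = 7.8e-05), without both libraries numbered 1 (2.0e-04) and with array weights (2.8e-04). In the same fits the hepatocyte call held as well (camera adjusted p = 0.017, 0.038 and 0.040). All of these are at the preset correlation. The iron storage subunits FTL and FTH1 averaged 1427 and 766 FPKM in NC, and 2166 and 823 FPKM in si-LINC01547, with 3849 and 1076 FPKM in replicate 1. The remaining 26 lists had camera adjusted p from 0.0711 to 0.894. Among them, the autophagy and immediate early lists had medians of 0.024 and 0.070 beside a lower camera direction. The cholesterol synthesis list, with 21 of 25 members lower and a camera adjusted p of 0.0979 with all libraries, fell without si-LINC01547 replicate 1 (2.1e-04, median -0.26), without both libraries numbered 1 (0.0057), with array weights (0.0054) and with the length and GC trend removed (0.030), each at the preset correlation; with all libraries its adjusted p = 0.502 with an estimated correlation. Fatty acid oxidation had 14 of 23 members higher with all libraries (camera adjusted p = 0.894, median 0.046; adjusted p = 0.958 with an estimated correlation). Its direction turned, and it fell, without si-LINC01547 replicate 1 (0.025, median -0.11), without both libraries numbered 1 (0.038) and with array weights (0.040), but not with the length and GC trend removed (0.893, median 0.12). The mitochondrially encoded list had a camera adjusted p of 0.101 and a median of -0.41 with all libraries (adjusted p = 0.645 with an estimated correlation), and 0.030 and -0.57 with the length and GC trend removed. Its median deviation from the NC mean was 0.58 in NC replicate 1 and -0.57 in si-LINC01547 replicate 1, and -0.31 to -0.24 in the other 4. Without both libraries numbered 1 the median was -0.026 and with array weights -0.056, beside a higher camera direction (adjusted p = 0.693 and 0.977). Fry's directional test called 0 lists, with a smallest adjusted p of 0.138. Fry's mixed test, for change in either direction, called the hepatocyte secreted list (adjusted p = 4.0e-04), with 0.0573 the next smallest, for the interferon list. Of the 5 hepatocyte genes tested, 1 had an unadjusted limma p under 0.05, VTN, which SARM1 partly overlaps. The mixed call may therefore rest on VTN alone.

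**Figure D3:**
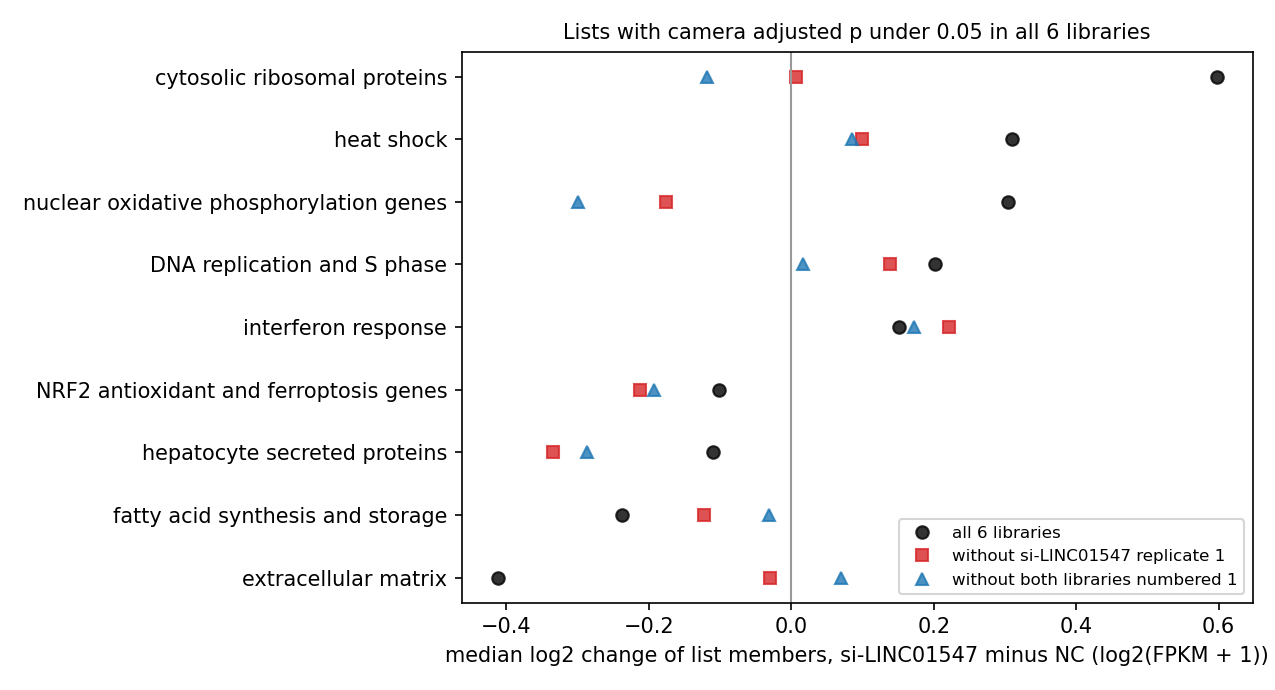
Median log2(FPKM + 1) difference, si-LINC01547 minus NC (horizontal axis), of the members of the 9 lists with a camera adjusted p under 0.05, with all 6 libraries (circles), without si-LINC01547 replicate 1 (squares) and without both libraries numbered 1 (triangles). The ribosomal protein median goes from 0.60 to 0.0065 and -0.12, and the interferon median from 0.15 to 0.22 and 0.17.

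Of 61 annotated genes within 500 kb of LINC01547, 16 were tested and 0 passed with limma, over all genes or adjusted over the list alone; 2 had an unadjusted p under 0.05. COL18A1, a basement membrane collagen on chromosome 21 from 45405137 to 45513720, averaged 2.69 ± 0.35 FPKM in NC and 1.04 ± 0.507 FPKM in si-LINC01547, and AP001505.1, a non-coding RNA from 44978832 to 44979274, 1.55 ± 0.341 and 2.57 ± 0.42 FPKM (SD, n = 3 each). The limma adjusted p was 0.894 for both.

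No red blood cell marker and no adipocyte or muscle marker reached a mean of 0.5 FPKM; HBB and ALAS2 stayed at or under 0.0991 and 0.239 FPKM, and ACTA1 and CKM at or under 0.486 and 0.173 FPKM. That mean was reached by 1 of 17 leukocyte, 5 of 15 fibroblast, 3 of 15 endothelial and 6 of 10 cholangiocyte markers. The genes named are the 2 most abundant of each list. Of the leukocyte markers CSF1R averaged 1.82 FPKM in NC and 1.44 FPKM in si-LINC01547, and CD14 0.252 and 0.389 FPKM, with CSF1R at 0.572 FPKM in si-LINC01547 replicate 1 and at 1.99 and 1.75 FPKM in replicates 2 and 3. Fibroblast markers COL1A1 and DES averaged 8.47 and 1.33 FPKM in NC, and 7.25 and 1.69 FPKM in si-LINC01547, with COL1A1 at 3.14 FPKM in si-LINC01547 replicate 1 and at 8.12 and 10.5 FPKM in replicates 2 and 3. DES was at 2.39 FPKM in si-LINC01547 replicate 1 and at 1.19 and 1.499 FPKM in replicates 2 and 3, and its log2 difference went from 0.20 to 0.024 without replicate 1. Endothelial markers EGFL7 and ESAM averaged 18.4 and 4.08 FPKM in NC, and 20.96 and 4.87 FPKM in si-LINC01547, with EGFL7 at 35.6 FPKM in si-LINC01547 replicate 1 and at 14.2 and 13.2 FPKM in replicates 2 and 3. Epithelial KRT7 and EPCAM, on the cholangiocyte list, averaged 33.6 and 14.4 FPKM in NC, and 24.1 and 31.3 FPKM in si-LINC01547. EPCAM was at 59.7 FPKM in si-LINC01547 replicate 1 and at 16.8 and 17.3 FPKM in replicates 2 and 3, and its log2 difference went from 0.82 to 0.24 without replicate 1 and to 0.12 without both libraries numbered 1.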

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

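The fits without both libraries numbered 1, with restricted maximum likelihood (REML) weights, with voom quality weights and with the length and GC trend removed were chosen after seeing the data. Counts of genes changed were 0 in limma under all settings except the weighted ones: 799 with array weights (287 higher, 512 lower), 2939 with REML weights that did not converge (1365 higher, 1574 lower) and 1334 with voom quality weights (583 higher, 751 lower), against 609 at an unadjusted p under 0.05 in the reported fit. List members changed were 72, 187 and 116, and neighbours of LINC01547 2, 7 and 6, under these weightings, against 0. NC replicate 3 had a weight of 5.63 with array weights and 5.61 with voom quality weights, and si-LINC01547 replicate 2 one of 11.9 with REML weights. As all weights were estimated from the same libraries, these counts may be too high. The log2 difference of LINC01547 stayed below 0 under each setting, and was past the threshold with these weightings only, at -1.07, -0.95 and -1.66; leaving out single libraries gave -1.40 to -1.09. Its 27 to 277 reads per library limit the precision of this value. Lists called went from 9 to 0 with an estimated correlation or with fry's directional test. They ranged from 7 to 11 without single libraries, and numbered 6 with array weights and 12 with libraries rescaled to the same total. For the 9 lists the correlation was estimated at 0.040 (NRF2) to 0.94 (ribosomal proteins), and why each call ended with an estimated correlation was not tested. With the replicate block the counts stayed at 0 genes and 9 lists and the LINC01547 difference at -1.25. Deviations of same-numbered libraries from their group mean correlated at -0.40, -0.46 and -0.15. Deviations cancel out within a group, so these values depend on each other and on the distance of si-LINC01547 replicate 1. They show no sign that the numbers pair the libraries, but cannot exclude it. Directions turned as follows, as log2 differences; the cause was not tested, and the weightings gave si-LINC01547 replicate 1 weights of 0.0591 to 0.0635. With array weights: extracellular matrix list 0.057, cytosolic ribosomal proteins list -0.022, nuclear oxidative phosphorylation genes list -0.22, LAMB3 0.057, RPL13A -0.16, ATP5F1B -0.18, NDUFS5 -0.32, FTL -0.043, FTH1 -0.055, COL1A1 0.098, EGFL7 -0.37 and CSF1R 0.092. Without both libraries numbered 1: extracellular matrix list 0.070, cytosolic ribosomal proteins list -0.12, nuclear oxidative phosphorylation genes list -0.30, PCNA -0.0015, LAMB3 0.13, RPL13A -0.27, ATP5F1B -0.20, NDUFS5 -0.43, FTL -0.11, FTH1 -0.19, COL1A1 0.13, EGFL7 -0.47 and CSF1R 0.19. With REML weights: LAMB3 0.035, RPL13A -0.15, ATP5F1B -0.13, NDUFS5 -0.50, FTL -0.10, FTH1 -0.29, EGFL7 -0.35 and CSF1R 0.15. With voom quality weights: LAMB3 0.056, RPL13A -0.15, ATP5F1B -0.18, NDUFS5 -0.32, FTL -0.042, FTH1 -0.054, COL1A1 0.11, EGFL7 -0.40 and CSF1R 0.15. With quantile normalization: HSP90AB1 -0.079, ATP5F1B -0.30, FTH1 -0.28 and EGFL7 -0.091. With libraries rescaled to the same total: FTH1 -0.0051 and EGFL7 -0.038. With the length and GC trend removed: AGPAT2 0.028, ATP5F1B -0.040 and FTH1 -0.063. Over the fits without single libraries these ranged: cytosolic ribosomal proteins list from 0.0065 to 0.93, nuclear oxidative phosphorylation genes list from -0.18 to 0.56, RRM1 from -0.23 to 0.079, F12 from -0.33 to 0.042, AGPAT2 from -0.31 to 0.17, RPL13A from -0.15 to 1.02, ATP5F1B from -0.21 to 0.26, NDUFS5 from -0.37 to 0.86, FTL from -0.11 to 0.69, FTH1 from -0.15 to 0.32, COL1A1 from -0.62 to 0.11, EGFL7 from -0.40 to 0.29 and CSF1R from -0.42 to 0.042. Of the other values, 133 of lists kept direction and call and 20 lost the call, while 663 of genes kept both and 40 passed the threshold under a weighting.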

Other observations

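The tests of the hepatocyte transcripts, of the word's splits and of the LINC01547 transcripts were chosen after the results were seen; the fits without single libraries were set beforehand, but using them to ask whether 1 library made the interferon result was chosen afterwards. Members of other lists stood apart when adjusted over their list alone, as limma values not passing over all genes; they were picked after their values were seen. CTH, an enzyme of cysteine synthesis, averaged 87.6 ± 20.1 FPKM in NC and 32.0 ± 5.98 FPKM in si-LINC01547, and PDIA3, a disulfide isomerase of the endoplasmic reticulum, 50.2 ± 9.53 and 19.7 ± 2.54 FPKM (SD, n = 3 each). EGLN1, an oxygen-sensing hydroxylase, averaged 51.0 ± 3.6 and 27.9 ± 0.329 FPKM, while ERO1A, an oxidoreductase, averaged 11.9 ± 0.701 and 20.1 ± 1.51 FPKM. SMAD2, a signal transducer of the TGF-beta pathway, averaged 7.50 ± 0.143 and 4.21 ± 0.0898 FPKM, and INHBE, an inhibin subunit, 3.83 ± 0.49 and 7.32 ± 1.01 FPKM. In each of these genes the 3 values of one group lay on one side of all 3 of the other.

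There are 10 ways to divide the 6 libraries into 3 and 3, too few for a share under 0.05. The real division gave 0 genes in limma, as did all 10 (highest other 0). With array weights it gave 799 genes and the division of NC replicate 1 with si-LINC01547 replicates 2 and 3 against the rest gave 2223, so that 2 of the 10 gave as many, which points to a structure of the samples. For lists the real division gave 9 and the highest other 10 (2 of 10 as many), and for genes apart by at least 1 log2 unit with no overlap 91 and 285 (3 of 10 as many). The camera p of the interferon list was 4e-06 in the real division and 0.0156 in the lowest of the others (1 of 10 as small). The camera adjusted p of that list was 1.1e-04 without si-LINC01547 replicate 1 and 6.5e-04 without NC replicate 1. None of these values separates loss of LINC01547 from other effects of the silencing RNA.

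The distance of si-LINC01547 replicate 1 from the others was weighed against 3 explanations. Its ribosomal protein transcripts deviated from replicates 2 and 3 by a median of 1.69 on the log2 scale (95% bootstrap interval 1.57 to 1.77), and by 1.57 (1.44 to 1.67) after a trend on gene length and GC content was removed, which argues against that trend as the whole source. Stronger silencing in this library would make its difference from replicate 3 go with that of replicate 2 from NC replicate 2. LINC01547 itself was lowest in this library, at 0.468 FPKM against 1.24 and 0.851 FPKM in replicates 2 and 3. The Pearson r across genes was -0.38, and -0.21 for replicate 1 minus 2 against replicate 3 minus NC replicate 3. The first uses NC replicate 2, whose deviation from its group mean goes with that of this library (r = 0.47), which lowers it. Both set replicates 2 and 3 on opposite sides, so anything these share apart from silencing lowers r too. Stronger silencing therefore stays undecided. RNA from cells of another type would bring transcripts of its own, and 1 protein-coding gene was at 10 FPKM or more in this library and under 0.5 FPKM in the others. A difference in RNA quality or in handling may remain, and was not tested.

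Transcripts typical of hepatocytes were near 0 in libraries labelled Hep3B. ALB and AFP stayed at or under 0.0545 and 0.0565 FPKM, and APOA1 and TTR were at 0 in all 6 libraries. Depth is argued against as the reason, as 3 reads of ALB correspond to at most 0.0409 FPKM. Of the 41 hepatocyte secreted genes, 3 had a mean of at least 1 FPKM. Such a count would be found if the cells were other than the labelled line, but also if this culture had lost hepatocyte expression. The values were seen first, and the count cannot tell these apart. Chosen after the values were seen, FOLR1 was at 1052 to 1938 FPKM, CGA at 164 to 485 FPKM, ALPP at 23.6 to 78.1 FPKM and MSLN at 51.7 to 108 FPKM. By mean level FOLR1 ranked 17 and CGA 82 among all genes. A loss of hepatocyte expression does not by itself account for high levels of other genes. Known Hep3B profiles were not compared, so the identity of the cells stays open.

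A scan of all 16384 words of 7 bases in the 3' UTRs of 10262 genes, chosen after seeing the data, gave CTGTTAA the lowest z, -11.93, in si-LINC01547 minus NC; the SD over words was 1.5. Genes with the word in the 3' UTR (1822) had a median log2 difference of -0.09, and those without it (8440) of 0.01. The z reached 11.93 in size in the real division and 6.965 in the next (1 of 10 as large), but other divisions put other words first, at up to 10.8. In the real division no word without CTGTTA passed 7.71 in size. Against the mean of NC replicates 2 and 3, z was -5.57, -14.08 and -10.77 in si-LINC01547 replicates 1 to 3, and -0.28 in NC replicate 1. As the word was picked from these same libraries, these values are not independent evidence. The word in coding sequence gave a z of -1.8, with 548 genes holding it there. This argues against base composition of the whole transcript as the whole source. The argument is limited, as fewer genes hold the word there and it was picked by its 3' UTR values, and both bring z nearer to 0. A candidate explanation is a small RNA whose seed pairs with CTGTTA, but of the 3 annotated LINC01547 transcripts 0 held CTGTTA or TAACAG, which argues against a silencing RNA that matches them at that seed with either strand. A small RNA of another origin, or one directed outside the annotated transcripts, stays open, as the sequence used is not given in the sources used here.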
